A study of Zea mays with 12 samples.

How the data were processed

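Total RNA from the roots of 40-day-old maize was sequenced in 12 libraries, 3 each for the control and for K, N and P deficiency. The deposited tables, 1 for each deficiency against the control, list 37385 genes. Per their names they were made with DESeq by the authors. The aligner, the genome build and the annotation are not given in the sources used here. The unit of the deposited per-library columns is FPKM per the file headers, and the control columns were identical in the 3 tables, so the 12 libraries stand on 1 scale. The deposited group means are normalized counts, a signal averaged by the authors over 3 libraries after division by a size factor per library. The deposited fold change is the ratio of the deficient to the control mean, and the authors' log2 column is its log2. The deposited p-value and adjusted p columns come from the authors' comparison. No per-library column was left unmatched to a sample (0 columns). Of the gene identifiers, 87.4% were found in the RefSeq gene table, and gene names and descriptions were taken from the deposited tables.

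The design planned edgeR on read counts, which was not used since the deposited per-library unit was FPKM. In its place limma 3.58.1 in R 4.3.3 was used, with an intensity trend and without robust weights, on log2(FPKM + 1). Genes with an FPKM of at least 0.5 in at least 3 of the 12 libraries were kept, which left 24311. One fit held all 12 libraries with group as its only term, and 6 comparisons were drawn from it, each adjusted by the Benjamini-Hochberg method with a threshold of 0.05 over all tested genes. An FPKM of exactly 0 can be a failed estimate by the authors: 0 to 13 genes per library were listed at 0 with at least 50 recovered reads. Folds in the text are ratios of mean FPKM. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

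The groups, the comparisons, 39 gene lists matched to gene names and descriptions, the rule for named genes and most of the alternatives were set before the data were examined. Lists with at least 5 tested members, 36 in number, were tested with limma's camera at a preset correlation of 0.01, again with the estimated correlation, and with fry. Annotation terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test, higher and lower genes apart, which takes genes as independent, adjusted per comparison and direction. The rule for named genes took, for each deficiency, the 8 higher and the 8 lower genes with the largest change among those that passed, with a mean in the upper part of tested genes, a description and no overlap between deficient and control libraries. It added the pair of members with the smallest p from each nutrient list and from each other list that passed, giving 42 names per comparison, of which the text gives most. Genes outside the rule are said to be chosen after their values were seen.

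Read counts per library were recovered from the deposited group means, which hold whole reads divided by a size factor. The size factors were found from genes whose group holds a single read. In the control the means of the 3 tables gave the reads of the 3 libraries directly, and in each deficient group the whole reads that give a gene's mean were searched, with FPKM as a guide for abundant genes. Recovery succeeded for 100% of control genes with a mean above 0, 99.9% in K deficiency, 99.96% in N deficiency and 99.9% in P deficiency; in the control, 99% of genes lay within 2.24e-09 of whole reads. Depth was 15226651 to 18465979 recovered reads per library. The recovered reads served for depth and for an added alternative, limma with voom weights on genes with at least 10 reads in at least 3 libraries. Between replicate libraries the squared difference over its counting variance averaged 16.1 to 45.8 per gene, a mean that abundant genes can carry.

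The fits were tested on simulated data with 200 changed genes placed in the libraries of 1 deficiency at a time, and counts drawn with each gene's mean and its spread pooled over the groups. At a change of 1 on the log2 scale limma recovered 40% of changed genes placed in K deficiency, 53% in N deficiency and 37% in P deficiency; at a change of 2 it recovered 72%, 76% and 72%. Of the simulated calls 6.67%, 4.44% and 6.84% were unchanged genes. The simulated genes were drawn independently, with no shifts shared by many genes, so these shares do not measure the rates in the real libraries. Replicate labels were checked as a pairing: 10 of 18 pairs of like-numbered libraries correlated above 0.1 across genes after removal of group means, from -0.39 to 0.33, and 3 of 12 libraries correlated best with their own number, so the replicates were not treated as pairs. Alternatives were other scalings of FPKM, filters, pseudocounts of 0.1 and 10, stricter thresholds, a replicate block, fits of the 6 compared libraries, and fits without each library in turn. Alternatives that need a negative binomial fit were left out.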

Results

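RNA sequencing of total RNA from roots of 40-day-old maize, line DengHai605, gave 12 libraries in 4 groups of 3. The control received nitrogen (N), phosphorus (P) and potassium (K) at normal levels, and each other group lacked adequate supply of 1 of these nutrients. The libraries of each group carry the replicate labels 1_3, 4_6 and 7_9, which the sources do not tie to separate plants. The p-value of a gene therefore measures the spread between these libraries. Camera at the preset correlation sets the genes of a list against other genes, and the term test counts called genes. Their p-values therefore do not measure that spread alone. Recovered depth was 17843853 to 18465979 reads in the control, 17232139 to 18390017 in K deficiency, 17299467 to 17957170 in N deficiency and 15226651 to 16609172 in P deficiency. Of 37385 genes listed, 24311 reached the expression minimum and were tested. Levels are FPKM, fragments per kilobase of transcript scaled to library size, as mean ± SD with n = 3 libraries, and log2 fold changes were fitted to log2(FPKM + 1), which understates the change of genes with low values. Across genes, Pearson's r between libraries was 0.959 to 0.980 within groups and 0.873 to 0.958 between groups, and genes are not independent replicates.

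**Figure D1:**
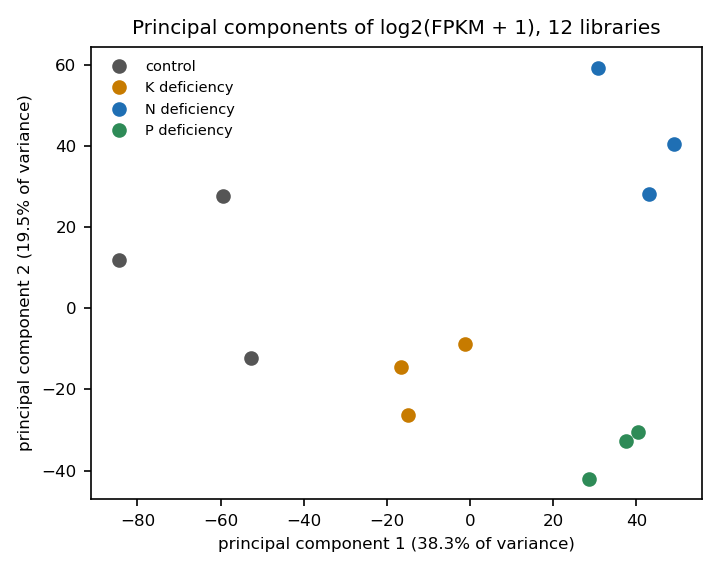
Each point is 1 of the 12 libraries, placed by the first principal components of log2(FPKM + 1), which hold 38.3% and 19.5% of the variance. The 3 control libraries lie at -84.4 to -52.8 on component 1, the K deficiency libraries at -16.6 to -1.28, and the N and P deficiency libraries at 28.6 to 49.1.

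The comparison of K deficiency with the control asked which root transcripts differ when potassium is short. Several stress protection transcripts that were abundant in the control fell. LOC100283639, described as embryonic protein DC-8, fell from 608 ± 230.2 to 11.2 ± 6.53 FPKM (54.4-fold), and mlg3 (gene 542216), a group 3 late embryogenesis abundant (LEA) protein, fell from 643 ± 239 to 17.2 ± 13.04 FPKM (37.4-fold). LEA proteins protect cells during water loss. The aldose reductase gene AR3 (gene 100857058), whose enzyme reduces sugars to sugar alcohols, fell from 330.2 ± 110.1 to 7.72 ± 3.8 FPKM. Among potassium genes, LOC100281406, a channel of the AKT2/3 type, rose from 2.72 ± 0.38 to 10.1 ± 0.582 FPKM (3.71-fold), and the transporter HAK20 (gene 103646532) rose from 2.41 ± 0.267 to 7.76 ± 3.4 FPKM.

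Other genes with large increases were LOC100284707, an elongation factor 1-alpha that delivers aminoacyl-tRNA to the ribosome, from 60.05 ± 6.88 to 438 ± 35.6 FPKM (adjusted p = 1.05e-05), and PCO109372 (gene 100193712), the large subunit of 3-isopropylmalate dehydratase in leucine synthesis, from 8.12 ± 0.907 to 58.05 ± 4.97 FPKM (adjusted p = 5.60e-06). LOC100125656, described as PL3K2, rose 15.7-fold, LOC100274152, related to the WAT1 transporter, rose 7.53-fold, LOC100283217, described as ATFP4, rose 7.66-fold and LOC100281170, described as loricrin, rose 5.54-fold. Blue copper protein LOC100280489 rose to 25.4 ± 23.6 FPKM and tropinone reductase LOC100284821 to 24.2 ± 21.5 FPKM, with a wide spread; neither passed under voom, in the authors' deposited table, without control replicates 1_3, 4_6 or 7_9, or without K deficiency replicates 4_6 or 7_9, and LOC100284821 not with a replicate block. Further genes with large decreases were LOC100285188, described as seed maturation protein PM41 (32.3-fold), LOC100278520 (30.6-fold, lost with a pseudocount of 0.1), gpm462 (gene 100286246), described as a stress-inducible membrane pore protein (27.01-fold), the anthocyanidin glucosyltransferase LOC100280876 (23.3-fold) and pco126369 (gene 100279493) (23.1-fold).

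The gene lists, fixed before the data were examined, placed these genes in groups. In the dehydrin and LEA list 11 of 30 members fell and 3 rose, among them LOC100286287, 17.3-fold lower, and LOC103641198, 46.8-fold lower. The dehydrin and LEA list had an adjusted p of 1.58e-05 by camera and 0.071 with an estimated correlation. Adjusted over the list alone, 12 fell and 4 rose. The members that rose were chosen here after their values were seen. The leaf polarity gene rld1 (gene 542515), whose name matched the list's text pattern, rose 1.46-fold. The group 2 LEA protein magi7438 (gene 100282984) rose 1.95-fold, and LOC100279368, described as of the LEA hydroxyproline-rich glycoprotein family, rose 2.45-fold. With an estimated correlation 0 lists passed in any comparison. In the heat shock and chaperone list 13 of 67 members fell (15 adjusted over the list alone) and 0 rose; hsp18a (gene 542293) fell from 24.7 ± 5.1 to 2.54 ± 1.13 FPKM and LOC100283886, a plastid small heat shock protein, fell 3.49-fold. The heat shock list had an adjusted p of 1.51e-05 by camera and 0.505 with an estimated correlation. In the abscisic acid list 4 of 10 fell (6 adjusted over the list alone), including IDP1977 (gene 100191697) and LOC103653298, both 8'-hydroxylases that break down the hormone. The abscisic acid list had an adjusted p of 1.58e-05 by camera and 0.071 with an estimated correlation. Sucrose and starch genes had 7 of 43 lower (10 adjusted over the list alone) and 1 higher. The sucrose synthase sus2 (gene 542091) fell from 141 ± 25.7 to 29.2 ± 3.81 FPKM, and ss1 (gene 541669), a starch synthase, fell 3.03-fold. Another sucrose synthase, sus1 (gene 542247), was chosen after its values were seen. It stood at 211 ± 27.9 FPKM in the control, 494 ± 99 in K deficiency and 452 ± 85 in P deficiency. The sucrose and starch list had an adjusted p of 0.014 by camera and 0.281 with an estimated correlation. Of 23 photosynthesis genes 5 fell, in the list alone also 5, including psah1 (gene 541685) and LOC100273427. The photosynthesis list had an adjusted p of 0.000336 by camera and 0.236 with an estimated correlation.

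Cellulose synthase genes moved the other way: 6 of 17 rose and 0 fell (8 adjusted over the list alone). The cellulose list had an adjusted p of 0.00159 by camera and 0.538 with an estimated correlation. cesa10 (gene 542685) rose from 62.7 ± 15.99 to 144 ± 38.8 FPKM and CesA12 (gene 542514) rose 2.29-fold. In the nitrogen assimilation list 5 of 13 rose (8 adjusted over the list alone), including the glutamine synthetases gln4 (gene 542214), from 152 ± 37.4 to 269.6 ± 24.6 FPKM, and gln5 (gene 542401), 1.58-fold. The nitrogen assimilation list had an adjusted p of 0.0492 by camera and 0.538 with an estimated correlation. In the potassium transport list 5 of 28 rose and 1 fell, 7 and 2 when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.701). In the phosphate transport and signalling list 3 of 17 rose and 2 fell (4 and 2 adjusted over the list alone), in the phosphate scavenging list 2 of 28 rose and 1 fell (5 and 2), and neither list passed (adjusted p = 0.239 and 0.211). LOC100191817, a glycerol-3-phosphate transporter, fell 7.65-fold, cl35113_1 (gene 100193704), with an SPX domain that senses phosphate status, fell 6.63-fold, and the acid phosphatase pco091084 (gene 100282868) fell 2.31-fold. The purple acid phosphatase pco116759 (gene 100283685) rose 1.38-fold, and, chosen after their values were seen, the phosphate transporters LOC732717 and LOC732718 rose 3.43-fold and 2.19-fold and the galactolipid synthase LOC100383973 rose 2.69-fold. Without control replicate 1_3, 0 cellulose, 0 nitrogen assimilation, 0 phosphate transport, 0 phosphate scavenging and 1 potassium transport genes passed as higher, and HAK20, cesa10, CesA12, gln4, gln5, rld1, pco116759, LOC732717, LOC732718 and LOC100383973 no longer passed. CesA12, gln4 and gln5 were also lost without control replicate 4_6 and without K deficiency replicate 1_3, cesa10 and rld1 without K deficiency replicate 1_3, magi7438 without control replicate 4_6 and without K deficiency replicate 1_3, and gln5 without K deficiency replicate 4_6. Without K deficiency replicate 1_3 pco116759, LOC732717, LOC732718 and LOC100383973 were lost, and all of these but pco116759 without K deficiency replicate 7_9. In the fit of the 6 libraries compared gln4, gln5, rld1, pco116759 and LOC732718 were lost, under voom gln5, rld1 and LOC732718, under median-ratio scaling rld1 and LOC732718, and with a replicate block LOC732718. In the authors' deposited table gln5, rld1, magi7438, pco116759 and LOC732718 did not pass. The nitrogen assimilation list was lost without K deficiency replicate 7_9 (adjusted p = 0.0686, within a range of 0.011 to 0.538 over its alternatives), and 2 members rose there and under voom.

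In total 2120 genes passed an adjusted p of 0.05 in K deficiency, 1174 higher and 946 lower, or 55.4% higher. The majority turned to lower genes under median-ratio scaling (45.4% higher), under voom (43.8%) and in the authors' deposited table (44.6%). It did so also without control replicate 4_6 (46.9%) and without K deficiency replicate 1_3 (46.5%). The count fell to 987 without control replicate 1_3, 1206 without K deficiency replicate 1_3 and 1321 without K deficiency replicate 7_9. Of the genes called, 1170 higher and 944 lower had no overlap between the 3 deficient and the 3 control libraries; over all tested genes 28.0% had none, where chance gives 10%. Annotation terms over-represented among higher genes included plant-type secondary cell wall biogenesis (14 of 64 genes, adjusted p = 0.0014), iron ion binding (37 of 295 genes, adjusted p = 0.000875) and phosphate ion transport (6 of 15 genes, adjusted p = 0.0102). Among lower genes they included iron-sulfur cluster assembly (8 of 23 genes, adjusted p = 0.00173) and response to stress (11 of 50 genes, adjusted p = 0.00173). With a library left out, iron-sulfur cluster assembly was lost in each of 6 cases and phosphate ion transport in all but that of K deficiency replicate 4_6. Secondary cell wall biogenesis was lost without control or K deficiency replicates 1_3 or 4_6, response to stress without control replicate 1_3 or K deficiency replicates 1_3 or 7_9, and iron ion binding without control or K deficiency replicate 7_9.

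N deficiency was compared with the control to find transcripts that differ when nitrogen is short. The high-affinity nitrate transporter genes nrt2 (gene 542092) and nrt2.2 (gene 606442) rose from 2.35 ± 0.528 to 55.5 ± 6.21 FPKM (23.7-fold) and from 1.62 ± 0.208 to 33.1 ± 7.41 FPKM (20.4-fold). sum1 (gene 542745), which makes the siroheme cofactor of nitrite reductase, rose from 19.1 ± 3.22 to 231 ± 36.4 FPKM (12.1-fold), and allantoinase LOC100274212, which releases nitrogen from purines, rose from 3.03 ± 0.329 to 29.6 ± 0.417 FPKM. The dehydrin gene dhn1 (gene 542373) fell from 5515 ± 1747 to 25.8 ± 23.2 FPKM (214-fold). Members of the phosphate scavenging list also fell. Purple acid phosphatase LOC100272946, which frees phosphate from organic compounds, fell from 70.1 ± 7.28 to 2.59 ± 0.76 FPKM. Glycerophosphodiester phosphodiesterase LOC100383215 fell from 183 ± 19.2 to 9.14 ± 2.15 FPKM.

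**Figure D2:**
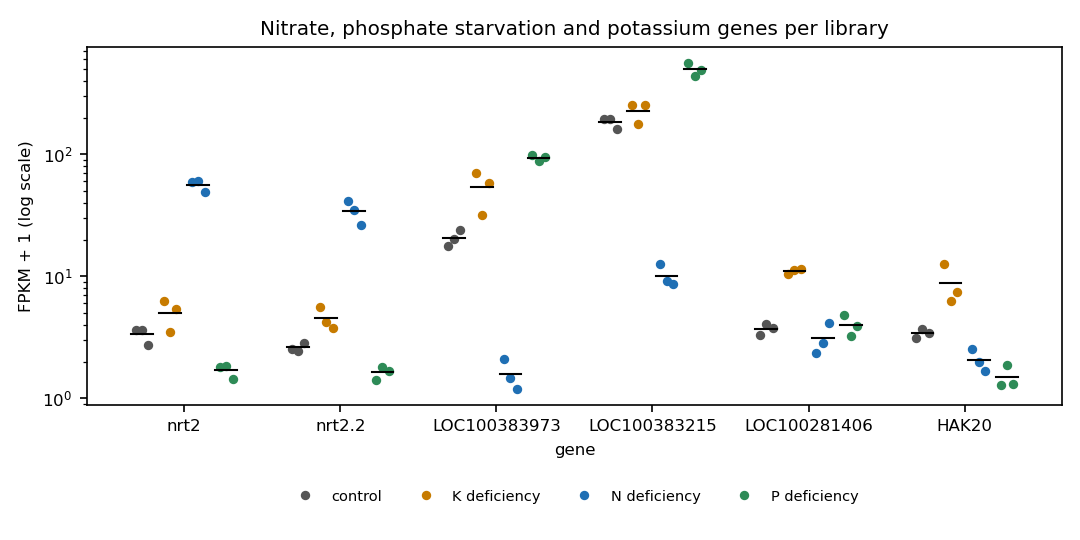
Points give FPKM + 1 on a log axis for each of the 12 libraries and black lines give group means, for 6 nutrient genes in the control and the K, N and P deficiency groups. The N deficiency libraries lie highest for nrt2 (48.4 to 59.5 FPKM) and lowest for LOC100383215 (7.71 to 11.6 FPKM), and the P deficiency libraries lie highest for LOC100383973 (87.1 to 97.1 FPKM).

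The largest increase among named genes was in RADIALIS (gene 100281018), with a MYB DNA-binding domain, from 0.589 ± 0.185 to 31.99 ± 4.12 FPKM (54.3-fold, adjusted p = 5.07e-07). LOC100284225, described as a proline-rich protein, rose to 18.2 ± 11.03 FPKM (11.9-fold), and was lost without control replicate 1_3, without N deficiency replicates 1_3 or 4_6, and under voom. Also higher were anthranilic acid methyltransferase LOC100500707 (13.1-fold), the RING finger protein LOC100281214 (10.8-fold), LOC100274152 (11.3-fold) and glucose-6-phosphate translocator LOC100281048 (10.1-fold). Beside dhn1, other large decreases were in LOC100283639 (129.8-fold), AY106518 (gene 100286330), a group 3 LEA protein (258-fold), mlg3 (95.5-fold), AR3 (139.5-fold), LOC100279044, a phosphatidylethanolamine-binding protein (112-fold), LOC100278520 (177-fold) and gpm462 (111-fold).

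In the nitrate and ammonium transport list 11 of 28 members rose and 2 fell, with 11 and 3 adjusted over the list alone. The nitrate and ammonium list had an adjusted p of 0.00239 by camera and 0.155 with an estimated correlation. NAR2.1, the partner protein of high-affinity nitrate transporters, was chosen after its values were seen and rose from 104 ± 6.33 to 320.2 ± 22.5 FPKM. In the nitrogen assimilation list 7 of 13 rose and 4 fell (8 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.158); the glutamine synthetase gene gln2 (gene 542400) fell from 41.9 ± 8.4 to 2.34 ± 0.855 FPKM. In the phosphate transport and signalling list 7 of 17 fell and 0 rose (7 and 1 adjusted over the list alone), among them LOC100501893, with an SPX domain, from 35.2 ± 7.09 to 1.34 ± 0.222 FPKM, and LOC100191817 (45.8-fold). The phosphate transport list had an adjusted p of 0.0115 by camera and 0.459 with an estimated correlation. The galactolipid synthase LOC100383973, which replaces phospholipids in membranes, fell from 19.6 ± 3.02 to 0.585 ± 0.464 FPKM, and the phospholipase D gene LOC100280155 fell 4.45-fold. The phosphate scavenging list, with 4 of 28 higher and 9 lower (5 and 9 adjusted over the list alone), did not pass (adjusted p = 0.0852), and 0 were higher without control replicate 1_3. Potassium transport genes included HAK24 (gene 100384841), 5.999-fold lower, and LOC100279933, 5.1-fold higher.

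Heat shock and chaperone genes fell in 30 of 67 cases and rose in 0 (34 fell and 3 rose adjusted over the list alone), with pco094428 (gene 100272911), a heat shock protein of the 70 kDa family, from 241 ± 39.7 to 4.55 ± 4.08 FPKM. The heat shock list had an adjusted p of 7.35e-09 by camera and 0.194 with an estimated correlation. In the dehydrin and LEA list 11 of 30 fell and 1 rose (13 and 2 adjusted over the list alone). The member that rose, chosen after its values were seen, was LOC100279368, 2.57-fold higher. The dehydrin and LEA list had an adjusted p of 0.000171 by camera and 0.128 with an estimated correlation. The abscisic acid list had 5 of 10 lower (5 adjusted over the list alone); LOC100285223, a phosphatase of the ABI1 type that holds back abscisic acid signalling, fell from 23.6 ± 9.44 to 0.51 ± 0.164 FPKM. The abscisic acid list had an adjusted p of 0.000271 by camera and 0.128 with an estimated correlation. Sucrose and starch genes had 13 of 43 lower and 2 higher (13 and 3 adjusted over the list alone), with sus2 25.01-fold lower. The sucrose synthase sus1, chosen after its values were seen, did not pass, at 234 ± 68.3 FPKM against 211 ± 27.9 in the control. The sucrose and starch list had an adjusted p of 0.0115 by camera and 0.194 with an estimated correlation. Of 23 photosynthesis genes 8 fell (8 adjusted over the list alone), psah1 by 25.7-fold. The photosynthesis list had an adjusted p of 0.000105 by camera and 0.153 with an estimated correlation. Of 17 cellulose synthesis genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with cesa2 (gene 542564) 2.42-fold higher and cesa3 (gene 542489) 2.01-fold lower. The cellulose list had an adjusted p of 0.00568 by camera and 0.515 with an estimated correlation.

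In the list of CBL and CIPK genes, calcium sensors and their kinases that act on nutrient transporters, 12 of 34 fell and 2 rose (12 and 3 adjusted over the list alone). The CBL and CIPK list had an adjusted p of 0.0195 by camera and 0.25 with an estimated correlation. The kinase LOC100141385 fell from 23.99 ± 1.05 to 1.8 ± 0.745 FPKM, and the sensor CBL2-1 (gene 100282538) rose 1.97-fold. Among antioxidant enzymes 6 of 21 fell and 1 rose (7 and 1 adjusted over the list alone), with the superoxide dismutases pco095461 (gene 100136885) and sod4 (gene 542722) 2.18-fold and 2.28-fold lower. The antioxidant list had an adjusted p of 0.024 by camera and 0.25 with an estimated correlation. Without control replicate 1_3, 4 CBL and CIPK genes passed as lower and 4 cellulose genes as higher.

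In total 4609 genes passed in N deficiency, 2341 higher and 2268 lower, or 50.8% higher. Lower genes were the majority under median-ratio scaling (47.9% higher), under voom (48.5%) and in the authors' deposited table (49.1%), among other settings. The count fell to 2765 without control replicate 1_3. Of the genes called, 2261 higher and 2245 lower had no overlap between the deficient and the control libraries; over all tested genes 34.2% had none, where chance gives 10%. Terms among higher genes included nitrogen metabolism (15 of 39 genes, adjusted p = 7.55e-05), phenylpropanoid biosynthesis (44 of 195 genes, adjusted p = 4.06e-06), heme binding (95 of 391 genes, adjusted p = 1.94e-13) and senescence-associated vacuole (9 of 10 genes, adjusted p = 6.64e-06). Terms among lower genes included response to heat (41 of 152 genes, adjusted p = 6.71e-07) and cellular response to phosphate starvation (13 of 37 genes, adjusted p = 0.0142). These terms passed with each library left out in turn.

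P deficiency was compared with the control to find transcripts that differ when phosphorus is short. LOC100285275, related to acid phosphatases, rose from 4.78 ± 0.228 to 15.99 ± 2.06 FPKM (3.35-fold), and phosphoenolpyruvate carboxylase LOC100384708, which feeds organic acid synthesis, rose from 3.49 ± 0.863 to 13.6 ± 2.62 FPKM (3.9-fold). Chosen after their values were seen, the galactolipid synthase LOC100383973 rose from 19.6 ± 3.02 to 93.03 ± 5.28 FPKM, the glycerophosphodiester phosphodiesterase LOC100383215 rose from 183 ± 19.2 to 496 ± 59.7 FPKM, and the phosphate transporter LOC732717 rose from 125 ± 26.9 to 431 ± 83.5 FPKM. The NADP malic enzyme gene me4 (gene 542209) fell from 55.3 ± 23.3 to 0.173 ± 0.0629 FPKM (319-fold), and AR3 fell from 330.2 ± 110.1 to 1.92 ± 0.942 FPKM.

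RADIALIS was again higher, from 0.589 ± 0.185 to 22.7 ± 1.24 FPKM (38.5-fold, adjusted p = 2.20e-06). Large increases with a wide spread between libraries were seen in LOC100284637, with a lysM domain that binds chitin-like sugars, to 366 ± 257 FPKM (19.7-fold), and in the phosphate transporter pht1-6 (gene 606432), to 279 ± 235 FPKM (19.4-fold). LOC100125656 rose 13.1-fold, and acyl carrier protein umc1491 (gene 100280455) rose 24.7-fold. LOC100284225, described as a proline-rich protein, rose 22.04-fold, glycosyltransferase LOC100382065 rose 28.7-fold, and LOC100284821 rose 15.5-fold. pht1-6 no longer passed without control replicate 1_3, without P deficiency replicates 4_6 or 7_9, or in the authors' deposited table, umc1491 was lost without control replicate 1_3, and LOC100284225 and LOC100382065 were lost under voom. Other large decreases were in LOC100283639 (117-fold), LOC100278520 (103-fold), mlg3 (86.4-fold), LOC100285188 (77.7-fold), dhn1 (60.4-fold), LOC100280949, described as a peripheral-type benzodiazepine receptor (72.5-fold), and the WD40 repeat protein LOC100274637 (104-fold).

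Many cytosolic ribosomal protein genes moved: 88 of 178 rose and 1 fell (135 and 1 adjusted over the list alone), with a median log2 fold change of 0.68. The ribosomal list had an adjusted p of 1.95e-15 by camera and 0.672 with an estimated correlation. LOC100284349, ribosomal protein L15, rose 1.9-fold and IDP245 (gene 100276789), ribosomal protein S10, rose 1.76-fold, though not in the fit of these 6 libraries alone. In the list of histones and cell cycle genes 30 of 63 rose and 3 fell (33 and 5 adjusted over the list alone); the cyclin-dependent kinase subunit LOC100280869 rose from 42.95 ± 7.74 to 73.9 ± 10.2 FPKM, and CycD5 (gene 732773) fell 5.37-fold; 7 fell under median-ratio scaling. The histone and cell cycle list had an adjusted p of 4.11e-05 by camera and 0.672 with an estimated correlation. Without control replicate 1_3, 4 ribosomal protein genes and 14 histone and cell cycle genes passed as higher, with a ribosomal list median of 0.64. With FPKM scaled to equal totals 58 ribosomal protein genes passed as higher.

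In the list of organic acid and phosphoenolpyruvate metabolism 11 of 35 rose and 3 fell (14 and 4 adjusted over the list alone), and the list was lost without control replicate 1_3 (adjusted p = 0.0695, within a range of 0.0367 to 0.672 over its alternatives), when 5 rose. The organic acid list had an adjusted p of 0.0382 by camera and 0.672 with an estimated correlation. The list's text pattern also took in 3-isopropylmalate dehydrogenases, enzymes of leucine synthesis. The phosphate scavenging list, with 9 of 28 higher and 3 lower, did not pass (adjusted p = 0.0521; 10 and 4 adjusted over the list alone), nor did phosphate transport and signalling, with 8 of 17 higher and 3 lower (adjusted p = 0.174; 8 and 3 adjusted over the list alone); without control replicate 1_3, 1 scavenging gene fell and 4 transport and signalling genes rose. Within them LOC100191817 fell 22.9-fold, cl35113_1 fell 13.5-fold and pco091084 fell 2.45-fold.

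The dehydrin and LEA list fell in 13 of 30 members and rose in 0 (13 adjusted over the list alone), including LOC103641198 (68.7-fold) and LOC100286287 (32.2-fold). The dehydrin and LEA list had an adjusted p of 1.24e-05 by camera and 0.123 with an estimated correlation. CBL and CIPK genes fell in 15 of 34 cases and rose in 1 (17 and 3 adjusted over the list alone), with the kinases LOC100381968 and LOC100281650 2.84-fold and 2.38-fold lower; 9 passed as lower without control replicate 1_3. The CBL and CIPK list had an adjusted p of 9.95e-05 by camera and 0.172 with an estimated correlation. NAC transcription factors fell in 13 of 48 cases and rose in 1, unchanged in number over the list alone, with NAC20 (gene 100216773) from 32.9 ± 7.57 to 3.24 ± 0.916 FPKM and NAC40 (gene 100281380) 2.88-fold lower. The NAC list had an adjusted p of 0.00848 by camera and 0.672 with an estimated correlation. Of 23 photosynthesis genes 7 fell (7 adjusted over the list alone), and 4 without control replicate 1_3. The photosynthesis list had an adjusted p of 0.0183 by camera and 0.631 with an estimated correlation. Heat shock genes went both ways, 11 of 67 higher and 16 lower (13 and 20 adjusted over the list alone), and the list did not pass (adjusted p = 0.0624); 7 passed as higher without control replicate 1_3. The abscisic acid list had 3 of 10 lower and 0 higher (3 and 1 adjusted over the list alone), a median of 0.12 and a mean of -0.52 on the log2 scale. The abscisic acid list pointed down by camera without passing (adjusted p = 0.244), while fry, which tests only whether members move one way on balance, gave an adjusted p of 0.00217. In the nitrogen lists the glutamine synthetase gene gln2 fell from 41.9 ± 8.4 to 7.29 ± 1.35 FPKM, fgs1 (gene 542710), a glutamate synthase, fell 2.37-fold, LOC100191837 of the NRT1/PTR family rose 2.67-fold and LOC100384152 of that family fell 3.34-fold. The potassium transporters HAK24 and HAK18 (gene 100191398) were 3.81-fold and 1.72-fold lower.

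In total 5691 genes passed in P deficiency, 3169 higher and 2522 lower, or 55.7% higher. The majority turned to lower genes with FPKM scaled to equal totals (42.5% higher), under median-ratio scaling (49.6%) and under voom (48.0%). It did so also in the authors' deposited table (45.2%), in the fit of the 6 libraries compared (49.5%) and without control replicates 1_3 (42.7%) or 4_6 (45.3%). The count fell to 2397 without control replicate 1_3, 3535 without P deficiency replicate 1_3, 3346 without P deficiency replicate 7_9 and 3714 without control replicate 4_6. Of the genes called, 2891 higher and 2488 lower had no overlap with the control; over all tested genes 39.2% had none, where chance gives 10%. Terms among higher genes included structural constituent of ribosome (156 of 387 genes, adjusted p = 6.43e-34), nucleosome (40 of 80 genes, adjusted p = 9.74e-12), glycolytic process (40 of 81 genes, adjusted p = 1.38e-11) and the MCM complex that unwinds DNA for replication (12 of 14 genes, adjusted p = 8.61e-07). Terms among lower genes included protein serine/threonine kinase activity (69 of 388 genes, adjusted p = 0.00727). The term test takes genes as independent, while the ribosomal list did not pass with an estimated correlation (adjusted p = 0.672). Without control replicate 1_3 the ribosome term had 14 genes higher (adjusted p = 1), and it, the MCM complex and kinase activity were lost there, without control replicate 4_6 and without P deficiency replicate 7_9. The ribosome and kinase terms were lost also without P deficiency replicate 1_3, while nucleosome and glycolytic process passed with each library left out. The ribosome term grew instead without control replicate 7_9, with 240 genes higher, and without P deficiency replicate 4_6, with 251 higher.

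**Figure D3:**
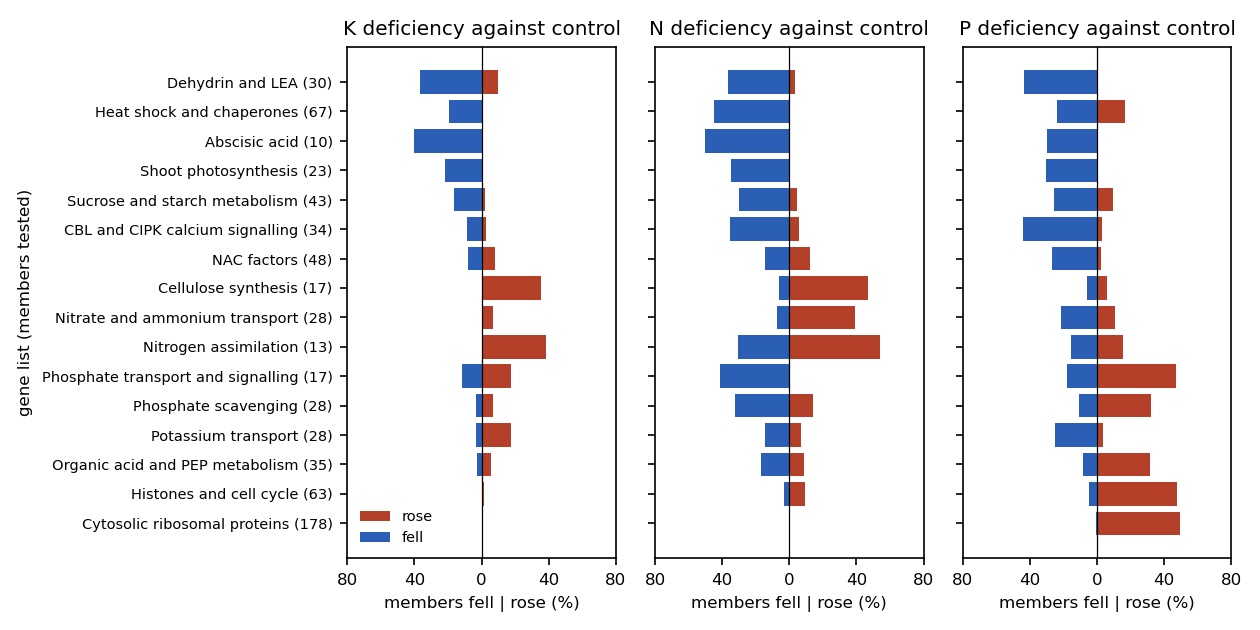
Bars give the percentage of tested members of 16 gene lists that rose (right) or fell (left) past an adjusted p of 0.05 in K, N and P deficiency against the control, with the number of members in brackets. Dehydrin and LEA genes fell in each comparison (11, 11 and 13 of 30), and of 178 ribosomal protein genes 88 rose in P deficiency, 1 in K deficiency and 0 in N deficiency.

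The 3 comparisons share their controls and many of their calls. Of the genes called, 327 were higher and 719 lower in all 3, and 450, 1885 and 3045 were called in K, N and P deficiency alone. The dehydrin gene dhn1 fell in each, to 288 ± 128 FPKM in K deficiency, 25.8 ± 23.2 in N deficiency and 91.4 ± 46.3 in P deficiency, from 5515 ± 1747. Other dehydrin genes, chosen after their values were seen, fell less. In the same order dhn2 (gene 542251) fell from 503 ± 88.9 to 177 ± 5.63, 218 ± 58 and 215 ± 56.5 FPKM. LOC100281087, dehydrin COR410, fell from 1045.5 ± 226 to 443 ± 83.7, 443 ± 216 and 384 ± 91.9. Its K deficiency call was lost without control replicates 1_3 or 4_6, without each K deficiency replicate, and with no filter. Its N deficiency call was lost without control replicate 1_3 and without N deficiency replicates 1_3 or 4_6. K and N deficiency shared 1361 calls in the same direction, against 201.3 if independent, K and P deficiency 1308 against 251.2, and N and P deficiency 2308 against 540.4. Without control replicate 1_3 these shared calls were 638, 580 and 1165, against 56.1, 48.6 and 137.9 if independent. Unchanged groups simulated 30 times against the same controls shared a median of 0, a value that holds no effects and so does not measure what the shared controls add to real ones. The covariance of log2 fold changes was 0.248, 0.260 and 0.374 in these pairs, against a simulated 0.0271, 0.0323 and 0.0393. Part of the excess of shared calls may come from the shared controls.

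**Figure D4:**
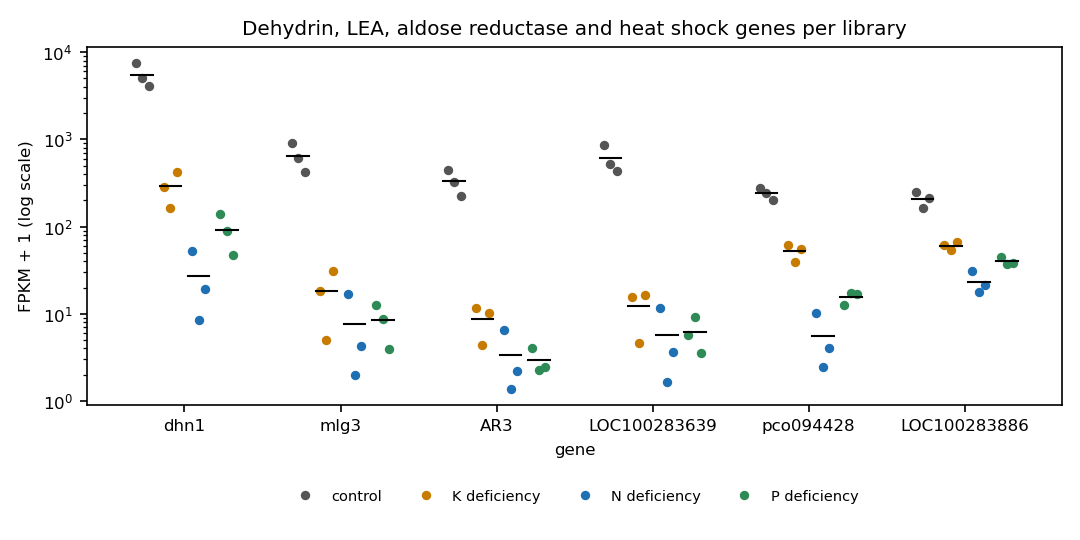
Points give FPKM + 1 on a log axis for each of the 12 libraries and black lines give group means, for 6 stress protection and heat shock genes in the control and the K, N and P deficiency groups. The dehydrin gene dhn1 lies at 4042 to 7446 FPKM in the control libraries, 163 to 418 in K deficiency, 7.45 to 51.9 in N deficiency and 46.6 to 139 in P deficiency.

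N and P deficiency were compared directly, since a difference between 2 responses needs its own test. The nitrate transporter nrt2 was higher in N deficiency by 5.06 on the log2 scale and nrt2.2 by 4.37. The galactolipid synthase LOC100383973 differed by -5.93, LOC100383215 by -5.63 and the phosphate transporter LOC732717 by -4.69, lower in N deficiency. Nitrate and ammonium transport genes were 9 of 28 higher and 1 lower in N deficiency (12 and 1 adjusted over the list alone). The nitrate and ammonium list had an adjusted p of 2.63e-05 by camera and 0.163 with an estimated correlation. Phosphate transport and signalling genes were 0 of 17 higher and 9 lower (1 and 11 adjusted over the list alone). The phosphate transport list had an adjusted p of 6.88e-06 by camera and 0.296 with an estimated correlation. Heat shock and chaperone genes were 2 of 67 higher and 24 lower in N deficiency (3 and 32 adjusted over the list alone). The heat shock list had an adjusted p of 2.30e-07 by camera and 0.337 with an estimated correlation. Ribosomal protein genes were 0 of 178 higher and 33 lower (1 and 157 adjusted over the list alone), with 8 lower without control replicate 1_3 and 6 without K deficiency replicate 7_9, libraries that enter only through the estimate of spread. The ribosomal list had an adjusted p of 2.34e-23 by camera and 0.411 with an estimated correlation. With FPKM scaled to equal totals 8 were lower, and under voom, which differs in more than scaling, 100 were. Altogether 2740 genes passed, 1409 higher and 1331 lower in N deficiency, or 51.4% higher and 69.9% with FPKM scaled to equal totals, and 14 of 36 lists passed. The count fell to 1755, 1355 and 1353 without N deficiency replicates 1_3, 4_6 and 7_9, and to 1331 and 1273 without P deficiency replicates 1_3 and 7_9.

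Against K deficiency, N deficiency again had lower phosphate transport and signalling genes, 0 of 17 higher and 8 lower (0 and 8 adjusted over the list alone), with 5 lower without K deficiency replicate 7_9. The phosphate transport list had an adjusted p of 0.000411 by camera and 0.559 with an estimated correlation. Heat shock genes were lower as well, 2 of 67 higher and 20 lower (3 and 24 adjusted over the list alone). The heat shock list had an adjusted p of 0.000319 by camera and 0.559 with an estimated correlation. Nitrate and ammonium transport genes were 6 of 28 higher and 2 lower (9 and 2 adjusted over the list alone). The nitrate and ammonium list had an adjusted p of 0.00242 by camera and 0.559 with an estimated correlation. In total 2384 genes passed, 943 higher and 1441 lower in N deficiency, with 1395 without K deficiency replicate 1_3, 1411 without K deficiency replicate 7_9, 1367 without N deficiency replicate 4_6 and 1556 without N deficiency replicate 7_9.

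Between P and K deficiency, the potassium transporter HAK20 was lower in P deficiency (log2 difference -2.51), and the potassium transport list had 1 of 28 higher and 5 lower (3 and 8 adjusted over the list alone). The potassium transport list had an adjusted p of 0.0255 by camera and 0.562 with an estimated correlation. Cellulose synthesis genes were 0 of 17 higher and 5 lower (1 and 8 adjusted over the list alone), with 3 lower without control replicate 1_3 and 2 without K deficiency replicate 7_9. The cellulose list had an adjusted p of 0.00804 by camera and 0.586 with an estimated correlation. Phenylpropanoid and lignin genes were 2 of 40 higher and 11 lower (3 and 14 adjusted over the list alone). The phenylpropanoid list had an adjusted p of 0.0141 by camera and 0.562 with an estimated correlation. In total 2245 genes passed, 717 higher and 1528 lower in P deficiency, or 31.9% higher and 20.2% with FPKM scaled to equal totals. The count fell to 1118, 1300 and 1114 without K deficiency replicates 1_3, 4_6 and 7_9, and to 1131 and 943 without P deficiency replicates 1_3 and 7_9.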

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

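The tests of control replicate 1_3, seed material, green tissue, both scalings, exchanged libraries and other splits were chosen after the result was seen, and those of short transcripts and of spread between libraries before it. The first pattern was first worded for heat shock and abscisic acid genes as well, and was narrowed to dehydrin and LEA genes after the results were seen.

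The direct comparisons drew attention because the effects of 2 deficiencies differed: 2740 genes differed between N and P deficiency, 2384 between N and K deficiency and 2245 between P and K deficiency. The 228 genes looked at were those named by the rule and the members of the nutrient lists. A pair of deficiencies was kept for a gene only if its calls against the control were opposite and its direct test passed. This kept 14 genes in 20 pairs. Values are log2 differences. In N minus P deficiency they were -5.39 for LOC100125656, -3.94 for LOC100191201, -2.61 for LOC100217133, -2.26 for LOC100274120, -2.14 for LOC100282424, -2.52 for LOC100285275, -5.63 for LOC100383215, -5.93 for LOC100383973, -4.69 for LOC732717, -3.45 for LOC732718, 5.06 for nrt2 and 4.37 for nrt2.2. In N minus K deficiency they were -5.63 for LOC100125656, -1.87 for LOC100282424, -5.04 for LOC100383973, -4.64 for LOC732717 and -2.59 for LOC732718. In P minus K deficiency they were -1.17 for HAK17, -2.51 for HAK20 and -1.46 for nrt2.2. Against the control, each K deficiency call behind the N minus K and P minus K values was lost without control replicate 1_3, but for LOC100125656, and so was the P deficiency call of LOC100191201. The calls of nrt2.2 in K and in P deficiency were lost also under voom and in the authors' deposited table, those of HAK17 in that table and in K deficiency with a replicate block, that of LOC732718 in K deficiency in both, that of LOC100125656 in N deficiency under voom and that of LOC100285275 in N deficiency in that table.

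Of 30 dehydrin and LEA genes 11, 11 and 13 fell in K, N and P deficiency against the control, and 3, 1 and 0 rose. Without control replicate 1_3 the list still passed camera in all 3 comparisons, the highest adjusted p being 4.5e-05, which argues against that library as the sole source; with an estimated correlation and all libraries it passed in none (adjusted p = 0.071, 0.128 and 0.123). Seed storage genes, 35 in number, summed to 218 to 254 FPKM in the control against 78.8 to 152 in the deficient libraries. They were led by the legumin-like cl2-1 (183 against 101) and a 16 kDa oleosin (42.3 against 1.07). Vicilin-like pco130570 (4.42 against 0.253) and globulin glb1 (1.07 against 0.057) were lower too. The test was narrowed after that sum was seen to zeins and globulins, whose 24 genes summed to at most 2.90 FPKM in a control library. The narrowing left out cl2-1, the oleosin and pco130570, so the low sum does not argue against seed material. Photosynthesis genes, 43 in number, summed to 71.4 to 88.3 FPKM in the control against 17.2 to 42.7 in the deficient libraries. The seed storage and photosynthesis sums were low beside dhn1 at 4042 to 7446 FPKM in the control, but both were higher there than in the deficient libraries. No seed or shoot library was measured to show how these genes stand beside dhn1 in such tissue. The sums therefore do not decide whether seed or green tissue contributed. A lower stress protection programme in roots short of a nutrient may be behind the pattern, as a hypothesis, and any unrecorded difference between the control and the other groups in growth or sampling stays open.

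Of 178 cytosolic ribosomal protein genes 88 rose in P deficiency against the control, with 4 without control replicate 1_3, and the list did not pass with an estimated correlation (adjusted p = 0.672). Scaling did not remove the shift, since the list median stayed at 0.58 or more under 2 other scalings and under voom, and short transcripts do not explain the whole of it, since 0% of 1000 lists matched on length and expression reached the list's 0.68. The matched lists had a median of 0.20 and at most 0.36, so part of the shift was shared by genes of like length and expression. Spread between libraries that moves all members together fits: the lowest P deficiency library, replicate 4_6 at 7.08, lay below the highest control library, replicate 7_9 at 7.21, a gap of -0.13 in median log2 FPKM. This shared spread remains a candidate cause of part or all of the shift, and a response to P deficiency stays open too.

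In the phosphate transport, phosphate scavenging and membrane lipid lists, with 17, 28 and 24 members, 8, 9 and 5 rose and 3, 3 and 9 fell in P deficiency, and 0, 4 and 1 rose and 7, 9 and 7 fell in N deficiency. The 9 genes that rose in P and fell in N deficiency were picked for moving so, and others did not: LOC100191817, cl35113_1, pco091084 and LOC100501893 fell in both, the last not in P deficiency without control replicate 1_3, and LOC100272946 fell in N deficiency without passing in P deficiency. An exchange of N and P deficiency libraries is argued against by nrt2 and nrt2.2, whose mean was 2.60 higher on the log2 scale in the lowest N deficiency library than in the highest other library. The other scalings multiply a whole library by 1 factor, and FPKM sums ran only from 573755 to 643745. They could therefore move these genes little. The median difference of the 9 stayed at -3.36 or lower under 2 other scalings and under voom, so these scalings do not account for a difference of that size. Of the 9, 9, 9 and 8 were still called both ways, and 8 each without control replicate 1_3 and without K deficiency replicate 7_9. Since the 9 were picked for such calls, these counts are no independent support. An opposite regulation of some phosphate genes by the supply of N and of P may account for the pattern, as a hypothesis, and unrecorded differences between the groups stay open.

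Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. Of these, 1 split, the real one, called as many genes in each comparison. The real split called 1606 genes for K deficiency, 3687 for N deficiency and 3417 for P deficiency against the control, with at most 0, 1 and 0 in another split. It called 1515 for N against P, 2117 for N against K and 1642 for P against K deficiency, with at most 0, 0 and 16.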

How the results depend on the processing

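The voom fit, the authors' deposited result, the settings of the direct comparisons, of the terms and of the overlaps, and the list tests without a library were chosen after seeing the data. Of 2268 values of named genes under the alternatives, 2154 kept their direction and side of the threshold, 114 kept their direction without passing and 0 reversed. These genes were picked from the same data for passing or for the smallest p, and the stricter thresholds reuse the main fit. The lack of reversals is therefore no independent support. Calls were lost for 16 of 126 values without control replicate 1_3 and for 10 of 42 without K deficiency replicate 1_3. Counts of genes stayed within 1.5 times their value under the other scalings, filters and pseudocounts, and under voom but for P against K deficiency, at 3387 genes. In the order K, N and P deficiency, N against P, N against K and P against K, an absolute log2 fold change of at least 1 gave 977, 2077, 2117, 905, 1223 and 849 genes and an adjusted p of 0.01 gave 829, 2366, 2075, 773, 974 and 532, stricter by construction. In fits of only the 6 libraries compared, with fewer samples, P deficiency gave 3417 and N against P gave 1515, and the authors' deposited table gave 3249 for P deficiency. With a library left out the counts ranged over 987 to 2329, 2765 to 4411, 2397 to 6306, 1273 to 3188, 1367 to 1899 and 943 to 2650. A replicate block gave 1938, 4536, 5556, 2769, 2394 and 2163, though the pairing check did not pair the replicates. With an estimated correlation 0 lists passed in each comparison, while fry, another question, passed 15 lists in P deficiency and 15 in N against K. Without control replicate 1_3 or K deficiency replicate 7_9 the lists that passed ranged over 6 to 8, 10 to 13, 7 to 7, 14 to 14, 5 to 5 and 7 to 7. Terms numbered 25 in K deficiency with no filter, 60 in P deficiency at an absolute log2 fold change of at least 1, and 17, 50 and 35 in K, N and P deficiency at an adjusted p of 0.01; without a library they ranged over 18 to 32, 52 to 90 and 38 to 124. Overlaps of K and N, K and P, and N and P were 582, 572 and 984 at an absolute log2 fold change of at least 1, 559, 509 and 1034 at an adjusted p of 0.01, and 1465 for N and P in the authors' deposited table. They ranged over 638 to 1538, 580 to 1650 and 1165 to 2664 without a library. Beyond stricter thresholds and fewer samples, the cause was not tested. The planned DESeq2 Wald test and the other edgeR normalization were not run, since the main test used the deposited FPKM. The recovered reads, which served for voom, were not put through them. Depth limits genes with few reads; between replicates the squared difference averaged 16.1 to 45.8 times its counting variance.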

Other observations

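The genes of this part were chosen after their values were seen. In the strigolactone list, too small for a test with 4 members, 3 rose in each deficiency, with medians of 1.30, 1.54 and 2.19 in K, N and P deficiency; adjusted over the list alone, 3 rose in each. Strigolactones are root hormones made by carotenoid cleavage. CCD8 (gene 100502522), a carotenoid cleavage dioxygenase, stood at 10.01 ± 0.216 FPKM in the control, 51.4 ± 4.4 in K deficiency, 67.6 ± 44.3 in N deficiency and 77.5 ± 17.3 in P deficiency. CCD7 (gene 100502521), another such enzyme, stood at 2.73 ± 0.654 in the control, 10.7 ± 2.67, 10.7 ± 6.99 and 20.4 ± 3.998; its K deficiency call was lost without control replicate 1_3, and in the authors' deposited table neither gene passed in N deficiency. The remaining riser, LOC100286117, a carotenoid cleavage dioxygenase, stood at 1.31 FPKM in the control and 3.54 in K deficiency, and its K deficiency call was lost without each of the 6 libraries compared, with no filter and with a pseudocount of 10. Phosphoenolpyruvate carboxylase kinase gene PPCK4 (gene 606429), whose product switches on the carboxylase, rose in P deficiency from 30.3 ± 8.68 to 166 ± 46.2 FPKM and fell in N deficiency to 3.37 ± 0.918.

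The iron store gene fer1 (gene 542553), a ferritin, fell from 198 ± 28.4 FPKM to 68.03 ± 7.88 in K deficiency, 51.2 ± 10.3 in N deficiency and 62.4 ± 5.68 in P deficiency. The zinc transporter umc1796 (gene 100281339) fell from 145 ± 31.02 to 56.8 ± 13.9, 28.8 ± 3.97 and 17.9 ± 3.38. The sulfate transporter gpm291 (gene 100193294) rose 1.82-fold, 2.07-fold and 1.89-fold, while LOC100382058, another sulfate transporter, rose 2.73-fold in K deficiency and fell in N deficiency from 25.5 ± 7.02 to 7.4 ± 0.343 FPKM. The expansin si606008c01 (gene 100282108), of a family that loosens cell walls, fell from 47.3 ± 12.2 to 8.64 ± 1.95, 3.98 ± 0.441 and 2.66 ± 0.79. The sugar transporter LOC103634637 of the SWEET family fell from 354 ± 121 to 104 ± 20.8, 64.5 ± 29.9 and 40.7 ± 2.85.

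Some libraries differed in their lowest counts or totals. K deficiency replicate 7_9 had 440 genes with a single recovered read, against 897 to 1080 in the other libraries, and 26596 genes with a read, against 27507 to 27982. The FPKM of the P deficiency libraries summed to 608975 to 643745, against 573755 to 596113 elsewhere, at the lowest recovered depths.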
